A study of Mus musculus with 18 samples.

How the data were processed

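PolyA RNA of wild-type mouse gastruloids was profiled by RNA-seq in 18 libraries, 3 replicates in each of 6 groups, per the labels. Gastruloids of a condition were pooled in a tube, frozen and extracted with on-column DNase digestion, and libraries were made with a stranded mRNA ligation kit, per the labels' protocols. The protocol text, the same for every sample, names a pair of library preparation codes and does not assign libraries to them, so a preparation batch could not be modelled. Groups, ages and pulse windows were taken from the treatment and stage labels. Library columns of both deposited tables matched the sample descriptions word for word, and 0 sample columns were left unused.

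Both kinds of value were made by the authors. Reads were trimmed with cutadapt 4.0 and aligned with STAR 2.7.8a to mm10, and Cufflinks 2.2.1 was run, per the submitters' processing notes, which name these tools and not their parameters. The deposited count table holds raw counts of 55385 genes, and the deposited FPKM table holds FPKM values, scaled by transcript length and library size, of 55468 genes. The counts were whole numbers. Of the genes, 86 were in the FPKM table alone and 3 in the count table alone. The counting tool's settings, such as its strand setting and its handling of reads on several loci, are not given in the sources used here. Gene identifiers were looked up in GENCODE release M21, which held 55144 of them, 54847 with the same coordinates. Coordinates are those of the deposited FPKM table.

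Counts were the main measure. Total counts ranged from 14841728 to 24536538 per library, and the 10 most abundant genes held 4.39% to 5.32% of a library. Genes were filtered with filterByExpr, which left 16041, and scaled by TMM. A negative binomial model with quasi-likelihood dispersion was fitted once over all libraries with 1 coefficient per group (edgeR 4.0.16, limma 3.58.1, R 4.3.3), and 11 contrasts were tested, 2-sided. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of F. Where a group is near 0 counts, this SE can understate the uncertainty. Against a group with 0 counts a fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts as a ratio with its exact 95% counting interval. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

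The contrasts were early against control at 48, 72 and 96 h, early against control at the end of each pulse and one day after it, each step of age within an arm, and 2 interactions. The choice of contrasts, lists, thresholds and most alternatives was made before the data were examined. A comparison of the early libraries of 96 h with the controls of 72 h, and an alternative without the 3 control libraries numbered 3, were added afterwards. Libraries were compared by Euclidean distance and principal components over the 1000 most variable genes, in log2 CPM with a prior count of 2. Replicate pairs were compared by a chi-square per degree of freedom over genes with at least 20 counts.

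From general knowledge, 34 gene lists of 365 names were written down: Wnt feedback and target genes, Wnt ligands, Nodal, BMP, FGF and ERK feedback, retinoic acid, and Notch and segmentation clock genes, naive, general, and formative and primed pluripotency, primitive streak, definitive and extraembryonic endoderm, presomitic mesoderm, somite, cardiac mesoderm, endothelium and blood, neuromesodermal and tailbud, neural, Hox groups 1 to 4, 5 to 9 and 10 to 13, epithelial adhesion, mesenchymal transition, primordial germ cell, two-cell-like, trophoblast, fibroblast and feeder, hypoxia and glycolysis, p53 response, immediate early and heat shock, proliferation, mitochondrially encoded and replication-dependent histone genes. Some genes stand in several lists. All names were matched in the count table, 10 histone names through their release M21 identifiers. Each list with at least 3 measured members was tested in each contrast with camera at a preset inter-gene correlation of 0.01, adjusted over 363 tests, then with an estimated correlation and with fry. Hox groups 10 to 13 had 2 measured members and were not tested as a list. Counts adjusted over the list alone used the p-values of its members only. Genes were named by rule: the 5 largest rises and falls with at least 5 CPM, separated libraries and a named gene, up to 4 members per list of the lowest adjusted p, members that moved against their list, and a panel of 28 genes fixed in advance. Some members that moved against their list are not reported here.

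Alternatives were DESeq2 size factors, no filter, a filter of 1 CPM, the DESeq2 1.42.0 Wald test, fits of only the groups compared, a replicate block, a 2-fold threshold, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the former also on all genes, and each library left out in turn. The fits were tested on simulated counts of 15734 genes, with changes placed in the early libraries of 48 h. Mean levels were those over all 18 libraries, and dispersions followed a fixed formula, so recovery in the real comparisons can differ. Limma-trend was run here on log2 values derived from CPM, not on FPKM. Of 50 genes changed by 1.5-, 2-, 4- and 8-fold, edgeR called 9, 28, 47 and 48, with 6 false calls, DESeq2 12, 28, 48 and 49, with 33 false calls, and limma-trend 7, 27, 45 and 47, with 5. Camera, with adjustment, called a raised list of 24 genes and 0 of 100 random lists, and fry passed 10 of these 100 without adjustment. The simulated genes were drawn independently of each other, so this does not test camera on lists of correlated genes. Splicing, variants and transcript isoforms were left out, since the deposited tables hold gene totals only.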

Results

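Messenger RNA was sequenced from mouse gastruloids, aggregates of embryonic stem cells that form germ layers and a body axis in culture. The cells were wild type, of the strain 129/SVEV. The 18 libraries fell into 6 groups of 3. Gastruloids received CHIR, an inhibitor of the kinase GSK3 that activates Wnt/β-catenin signalling, as a pulse either between 48 and 72 h after aggregation (control) or between 24 and 48 h (early). Each arm was collected at 48, 72 and 96 h, so the controls of 48 h were untreated, and the early libraries of 48 h and the control libraries of 72 h mark the end of each pulse. Per the series' labels the question was how the timing of the Wnt pulse changes gene expression. Total counts per library ranged from 14841728 to 24536538, and 16041 genes were tested. Levels are given in CPM (counts scaled to the TMM-adjusted library size) ± SD and changes as log2 fold changes ± SE, with n = 3 libraries per group throughout. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

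All 18 libraries lay nearest to the other libraries of their own group in the 1000 most variable genes. The first principal component held 72.5% of the variance, the second 11.3% and the third 7.96%. By mean Euclidean distance to a group's mean profile in log2 CPM, the early libraries of 48 h were nearest among the controls to those of 48 h (53, against 73.6 for the controls of 72 h and 127 for those of 96 h). Early libraries of 72 h were also nearest to the controls of 48 h (43.5, against 57.3 and 113.9). By 96 h, the early libraries lay nearest to the controls of 72 h, at 33.0, with 69.0 to the controls of 48 h and 91.4 to those of their own age. Distances of single libraries to the others of their group were 11.7 to 33.05, the last for control replicate 3 of 96 h. In log2 CPM the early libraries of 96 h lay at 33.0 from the controls of 72 h and 39.9 from the early libraries of 72 h. On log2(FPKM + 1) these mean distances were close, at 31.3 and 32.7.

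**Figure D1:**
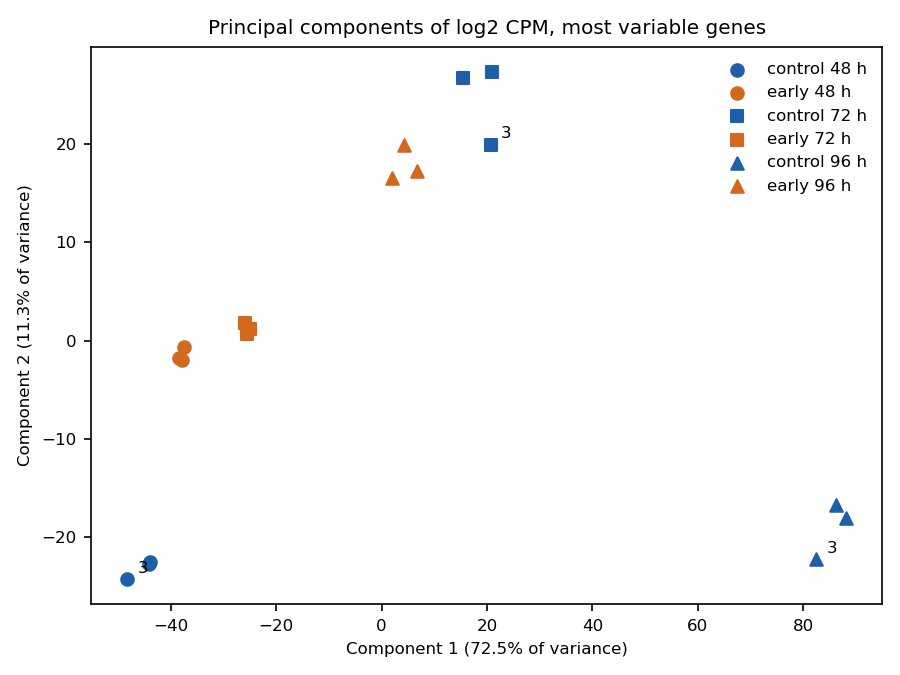
Principal components 1 and 2 of log2 CPM over the 1000 most variable genes, with 1 point per library, coloured by pulse and shaped by age, and the percent of variance on each axis. The early libraries of 96 h sit beside the controls of 72 h, and the control libraries numbered 3 are marked.

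Control replicate 3 stood apart from replicates 1 and 2 at each age. Its counts differed from theirs by a chi-square per degree of freedom of 15.4 to 15.6 at 48 h, 16.2 to 19.1 at 72 h and 24.6 to 28.1 at 96 h, where all other replicate pairs gave 1.41 to 7.90. In control replicate 3 at 72 h, 7 of the 7 Hox genes of groups 1 to 4 with at least 1 CPM were above both other libraries and 11 of 12 primitive streak genes were below both. At 96 h, 10 of 12 Hox genes of groups 5 to 9 and 12 of 14 tailbud genes in control replicate 3 were above both, and 8 of 9 presomitic genes and 6 of 6 somite genes were below both. Eomes was at 125, 123 and 26.3 CPM in control replicates 1, 2 and 3 at 72 h, and Tbx6 at 243, 261 and 98.5 CPM at 96 h. At 48 h, 6 of 7 Nodal pathway genes and 6 of 6 mitochondrially encoded genes were above both. Of libraries that do not differ, each would be above both others at 1 of 3 genes and below both at 1 of 3. No pair of replicates within a group held identical values, and no libraries were merged.

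The step of the controls from 48 to 72 h spanned their pulse and shows what changed over it. T, the brachyury factor of the primitive streak and tailbud, rose from 0.593 ± 0.258 to 1048 ± 198 CPM (log2 fold change 10.81 ± 0.28, adjusted p = 1.40e-15). Axin2, a negative feedback regulator of Wnt signalling, rose 16.99-fold from 12.7 ± 0.907 to 215 ± 18.7 CPM (4.09 ± 0.07, adjusted p = 1.96e-17). Sp5, a direct Wnt target, was at 0 in all 3 untreated libraries and at 52.1 ± 3.81 CPM at 72 h, at least 967-fold higher against a floor of 3 counts over the group, and Cdx1, a caudal homeobox factor, was at least 1232-fold higher. Without control replicate 3 of 72 h Cdx1 was at least 745-fold higher, its levels being 31.3, 49.1 and 132 CPM in replicates 1, 2 and 3. Such floors, and the intervals of ratios given below, cover counting error only, and leaving out a library of a group at 0 lowers a bound with the reads counted (for Sp5, to 614 without control replicate 2 of 48 h). Evx1, a factor of the posterior streak, rose by 8.87 ± 0.51 and Mixl1, of mesendoderm, by 6.62 ± 0.73. Nanog, of the pluripotent state and the posterior epiblast, rose from 42.99 ± 5.87 to 299 ± 51.5 CPM (2.80 ± 0.12), whereas Pou5f1 did not pass the test (0.10 ± 0.22, adjusted p = 0.727).

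Of the fixed lists, 13 of 14 Wnt feedback and target genes rose (adjusted p = 2.08e-07, and adjusted p = 0.0156 with an estimated correlation), with Tnfrsf19 at 4.79 ± 0.11 and Nkd1 at 3.33 ± 0.12 among them. Wnt ligands rose in 7 of 8 cases (adjusted p = 1.67e-04, and adjusted p = 0.0305 with an estimated correlation), led by Wnt8a (6.72 ± 0.30) and Wnt3a (6.04 ± 0.35, and 6.74 without control replicate 3 of 48 h). Primitive streak genes rose in 11 of 13 (adjusted p = 5.93e-05, and adjusted p = 0.297 with an estimated correlation). Tailbud genes, which mark neuromesodermal progenitors, rose in 13 of 14 (adjusted p = 2.05e-07, and adjusted p = 0.068 with an estimated correlation), including Nkx1-2 (8.10 ± 0.27) and Cdx2 (7.34 ± 0.52). Hox genes of groups 1 to 4, anterior members of the clusters that pattern the body axis, rose in 8 of 12 (adjusted p = 0.0139, and adjusted p = 0.453 with an estimated correlation), and 1 of 12 genes of groups 5 to 9 did (adjusted p for the list = 0.612). Control replicate 3 of 72 h was above both others at 7 of 7 Hox genes of groups 1 to 4, and without the 3 control libraries numbered 3 that list still passed (adjusted p = 0.0164). Hoxa5 (adjusted p = 0.00817) was at 0, 0.313 and 4.87 CPM in control replicates 1, 2 and 3 of 72 h and was not called without control replicate 3 of 72 h (adjusted p = 0.104) or on log2(FPKM + 1) (0.116).

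Formative and primed epiblast genes fell over the same step, 10 of 14 with 1 rise (adjusted p = 0.00108, and adjusted p = 0.0496 with an estimated correlation). Control replicate 3 of 72 h was below both others at 9 of 13 formative genes with at least 1 CPM and above both at 4. Foxd3 (-6.63 ± 0.21), Pou3f1 (-4.09 ± 0.10) and Otx2, a homeobox factor of the anterior and primed epiblast (-2.89 ± 0.16), were among those that fell, and Fst, an activin antagonist, rose (4.47 ± 0.24). General pluripotency genes fell in 7 of 10 (adjusted p = 0.0143, and adjusted p = 0.30 with an estimated correlation), including Utf1 (-2.76 ± 0.15) and Sox2 (-2.15 ± 0.25). Epithelial adhesion genes fell in 8 of 12 (adjusted p = 0.0269, and adjusted p = 0.347 with an estimated correlation), with Krt18 at -1.76 ± 0.14. Proliferation genes fell in 11 of 12 (adjusted p = 2.14e-05, and adjusted p = 0.068 with an estimated correlation) by small amounts, such as -0.53 ± 0.04 for Mcm2. Hypoxia and glycolysis genes fell in 9 of 14 and rose in 2, Eno1 and Vegfa (adjusted p = 0.0426, and adjusted p = 0.484 with an estimated correlation). Naive pluripotency genes moved both ways, 6 up and 5 down of 15 (adjusted p = 0.817). Among the largest falls outside the lists were the cytokine genes Il10 (-5.27 ± 0.25) and Tnfsf11 (-4.93 ± 0.23). In all, 4989 genes rose and 4859 fell, 3328 of them by at least 2-fold, and the libraries of both groups were separated at 66.01% of tested genes, where chance gives 10%. Adjusted over the list alone, 10 hypoxia genes fell and the other called lists kept their counts. On the log2(FPKM + 1) scale, 61.9% of called genes were higher, against 50.7% on counts.

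The step from 72 to 96 h shows the day after the control pulse. Tbx6, which specifies presomitic mesoderm, rose from 1.59 ± 0.351 to 201 ± 88.96 CPM (6.96 ± 0.34, adjusted p = 1.05e-11), and Msgn1, another factor of that tissue, from 0.339 ± 0.383 to 148 ± 88.9 CPM (8.68 ± 0.60, adjusted p = 1.12e-09, and 10.23 without control replicate 2 of 72 h). Meox1, of somites, rose 265-fold (95% interval 90.5 to 1289), 169.8-fold (57.9 to 825) without control replicate 2 of 72 h and 566-fold (101 to 22385) without control replicate 3 of 72 h. Cdx2, a caudal factor of the tailbud, rose to 283 ± 70.3 CPM (3.54 ± 0.22), and Aldh1a2, which makes retinoic acid, by 8.17 ± 0.75. Nodal, the ligand that induces mesendoderm, fell from 117 ± 38.8 to 8.38 ± 2.53 CPM (-3.77 ± 0.23), Nanog to 24.6 ± 4.65 CPM (-3.59 ± 0.13) and Eomes, an early streak factor, to 2.45 ± 1.66 CPM (-5.12 ± 0.49). T fell to 625 ± 139 CPM (-0.75 ± 0.15) and Pou5f1 to 351 ± 172 CPM (-1.93 ± 0.23).

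All 12 measured Hox genes of groups 5 to 9 rose (adjusted p = 2.05e-07, and adjusted p = 0.111 with an estimated correlation), as did all 12 of groups 1 to 4 (adjusted p = 2.29e-06, and adjusted p = 0.122 with an estimated correlation). Hoxc8 was at 0 at 72 h and at least 450.4-fold higher at 96 h, with 1.54, 1.79 and 88.9 CPM in control replicates 1, 2 and 3 of 96 h, and Hoxd3 and Hoxd4 were at least 137-fold and 140.3-fold higher. Without control replicate 3 of 96 h Hoxc8 was at least 29.3-fold higher, and without control replicate 1 of 96 h at least 752-fold. With only the groups compared Hoxc8 was not called (adjusted p = 0.0556). Presomitic genes rose in 8 of 11 (adjusted p = 4.98e-05, and adjusted p = 0.164 with an estimated correlation). Notch and segmentation clock genes rose in 9 of 11 with Hes1 falling (adjusted p = 1.22e-05, and adjusted p = 0.0156 with an estimated correlation). Somite genes rose in 5 of 8 with Pax1 falling (adjusted p = 0.0144, and adjusted p = 0.327 with an estimated correlation). Hes7, the clock oscillator, rose by 8.26 ± 0.25 from a low level of 0.413 ± 0.304 CPM, and Dll1, a Notch ligand, by 5.25 ± 0.26. All 9 retinoic acid genes rose (adjusted p = 7.23e-06, and adjusted p = 0.038 with an estimated correlation), all 11 mesenchymal transition genes rose (adjusted p = 1.22e-05, and adjusted p = 0.064 with an estimated correlation), including Cdh2 (2.93 ± 0.11) and Fn1 (2.81 ± 0.25), and tailbud genes rose in 13 of 14 (adjusted p = 5.03e-05, and adjusted p = 0.14 with an estimated correlation), T being the member that fell. Neural genes rose in 6 of 10 (adjusted p = 0.0112, and adjusted p = 0.347 with an estimated correlation), among them Neurog2 (5.19 ± 0.62, and 6.50 without control replicate 3 of 72 h). FGF and ERK feedback genes rose in 8 of 11 (adjusted p = 0.0318, and adjusted p = 0.109 with an estimated correlation), including Fgf4 (3.39 ± 0.12), with Etv5 and Spry1 falling.

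In these controls formative genes fell in 9 of 14 (adjusted p = 3.25e-05, and adjusted p = 0.0269 with an estimated correlation), with Fgf5, an epiblast growth factor, at -4.54 ± 0.33 and Otx2 at -3.55 ± 0.26. Naive genes fell in 9 of 15 (adjusted p = 0.00814, and adjusted p = 0.367 with an estimated correlation), while Prdm14 (2.79 ± 0.40) and Klf5 (1.33 ± 0.25) rose. Nodal pathway genes fell in 7 of 8 (adjusted p = 3.48e-04, and adjusted p = 0.0699 with an estimated correlation), including the co-receptor gene Tdgf1 (-3.60 ± 0.28). Epithelial adhesion genes fell in 10 of 12 (adjusted p = 1.67e-04, and adjusted p = 0.112 with an estimated correlation), against Krt8, which rose (1.07 ± 0.20). The p53 response list fell in 7 of 11 (adjusted p = 0.00719, and adjusted p = 0.068 with an estimated correlation), with Cdkn1a at -1.25 ± 0.06 and Phlda3 rising (0.51 ± 0.11). Wnt feedback and target genes rose in 10 and fell in 2, Tcf7 and Znrf3, of 14 (adjusted p = 0.0535). In total 4410 genes rose and 4392 fell, 2676 by at least 2-fold, and 56.03% of tested genes separated the groups against 10% by chance. Beside these lists stands control replicate 3 of 96 h, above both other libraries at 10 of 12 Hox genes of groups 5 to 9, 12 of 14 tailbud and 9 of 10 neural genes, and below both at 8 of 9 presomitic, 6 of 6 somite, 9 of 11 mesenchymal and 9 of 12 epithelial genes, where 1 of 3 would be expected. Without the 3 control libraries numbered 3 the naive list did not pass (adjusted p = 0.0685). Adjusted over the list alone, 10 formative genes fell and no other called list changed its counts.

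**Figure D2:**
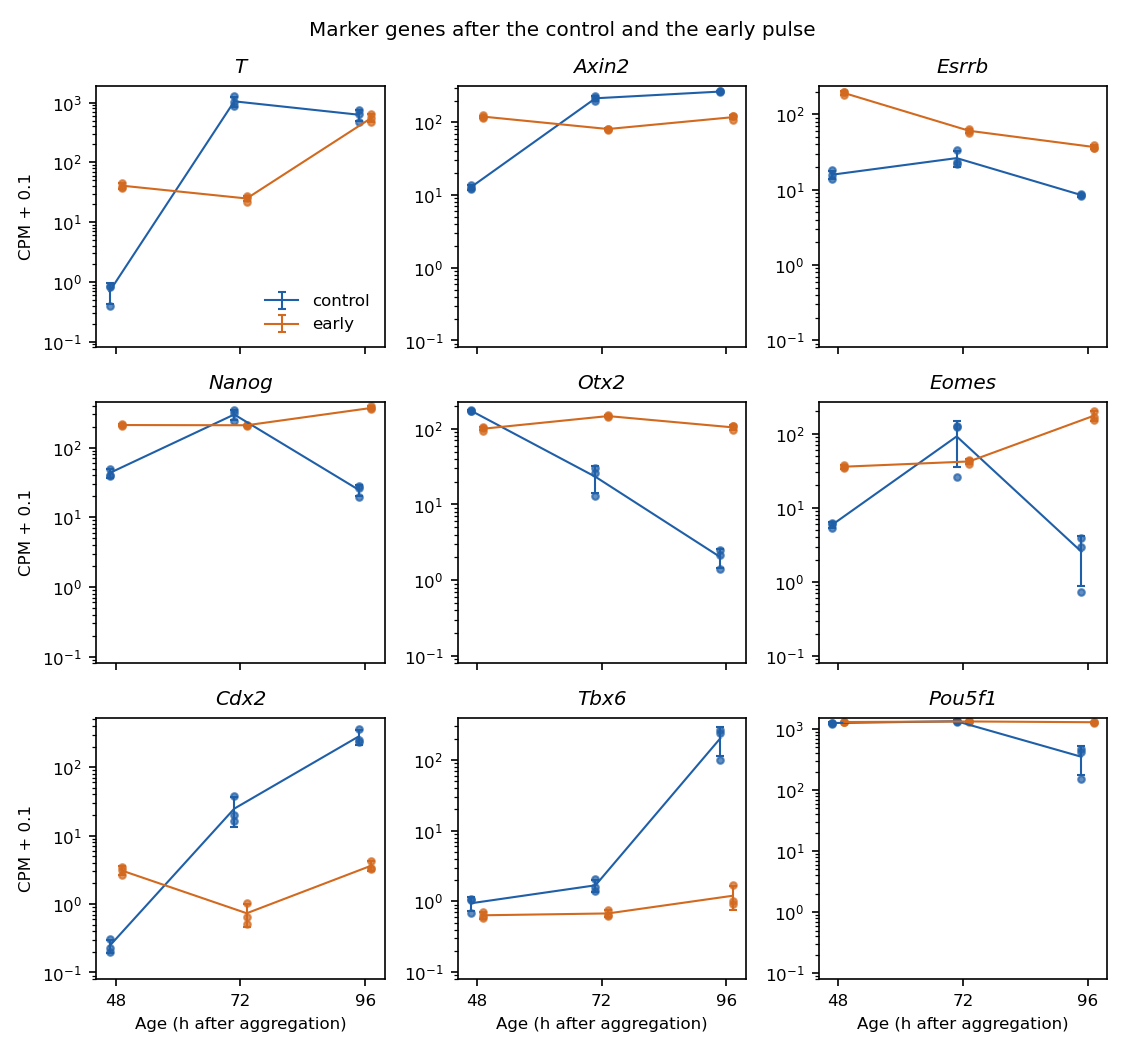
CPM (log axis, 0.1 added) of 9 genes at 48, 72 and 96 h after aggregation, with 1 point per library, a line through the group means and bars for the SD (n = 3). T peaks at 1048 CPM in the controls at 72 h and reaches 554 CPM after the early pulse at 96 h, where Tbx6 stays at 1.104 CPM.

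The comparison at 48 h asks what had changed by the end of the early pulse, against untreated controls. Naive pluripotency genes were higher after the early pulse in 15 of 15 cases (adjusted p = 1.38e-11, and adjusted p = 0.038 with an estimated correlation, median log2 fold change 2.60). Esrrb, an orphan nuclear receptor of naive cells, was at 191 ± 11.1 CPM against 15.7 ± 2.07 (3.62 ± 0.12, adjusted p = 7.01e-14), Zfp42 at 161 ± 1.83 against 30.6 ± 2.299 (2.40 ± 0.08) and Tbx3 was higher by 4.01 ± 0.23. T was at 40.6 ± 4.26 CPM against 0.593 ± 0.258 (6.12 ± 0.33, adjusted p = 4.75e-11). Axin2 was 9.49-fold higher (3.25 ± 0.07), Sp5 at least 170.4-fold and Cdx1 at least 111-fold higher, and Hoxb1 was higher by 6.92 ± 1.42 (7.62 without control replicate 3 of 48 h).

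Wnt feedback and target genes were higher in 11 of 14 (adjusted p = 2.33e-06, and adjusted p = 0.0231 with an estimated correlation). Wnt ligands were higher in 6 of 8 (adjusted p = 0.00568, and adjusted p = 0.064 with an estimated correlation), with Wnt8a at 5.26 ± 0.31 and Wnt4 lower (-1.92 ± 0.66). Wnt4 was not called on log2(FPKM + 1) of all genes (adjusted p = 0.418), nor without control replicate 1 (adjusted p = 0.0803) or 2 (0.0502) or early replicate 2 (0.0874) of 48 h. Nodal pathway genes were higher in 7 of 8 (adjusted p = 3.58e-04, and adjusted p = 0.0699 with an estimated correlation), among them Lefty1 and Lefty2, inhibitors of Nodal (2.49 ± 0.21 and 2.49 ± 0.16). Tailbud genes were higher in 9 of 14, with Greb1 lower (adjusted p = 3.40e-05, and adjusted p = 0.129 with an estimated correlation). Streak genes were higher in 7 of 13 (adjusted p = 0.00316, and adjusted p = 0.456 with an estimated correlation). Hox genes of groups 1 to 4 were higher in 4 of 12 (adjusted p = 0.033, and adjusted p = 0.531 with an estimated correlation). Formative genes were lower in 10 of 14 (adjusted p = 7.48e-04, and adjusted p = 0.0439 with an estimated correlation), including Pou3f1 (-2.96 ± 0.09) and Fgf5 (-1.67 ± 0.24), and higher for Fst and Etv1. Epithelial adhesion genes were lower in 11 of 12 (adjusted p = 1.93e-06, and adjusted p = 0.0622 with an estimated correlation), with the keratin gene Krt18 at -2.98 ± 0.15 and Cldn7 at -1.71 ± 0.13. Fibroblast and feeder genes, a check for other cells, were lower in 4 of 7 (adjusted p = 0.0183, and adjusted p = 0.0896 with an estimated correlation), control replicate 3 of 48 h being above both others at 4 of 4 members. Without the 3 control libraries numbered 3 this list still passed (adjusted p = 0.0187). Outside the lists, Ntn1, a guidance cue, was higher by 6.13 ± 0.22 and Irs4, an insulin receptor substrate, lower (-3.89 ± 0.11).

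In this comparison 3694 genes were higher and 3320 lower after the early pulse, 1854 by at least 2-fold, with 56.1% of tested genes separating the groups against 10% by chance. On the log2(FPKM + 1) scale 41.8% of called genes were higher, against 52.7% on counts. When p-values were adjusted over the list alone, 10 tailbud genes and 2 Hox genes of groups 1 to 4 were higher and the other called lists kept their counts.

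The comparison at 72 h asks how the arms differed at an equal age, one day after the early pulse and at the end of the control pulse. T was at 24.8 ± 2.58 CPM against 1048 ± 198 (-5.41 ± 0.18, adjusted p = 3.07e-13), Axin2 at 81.01 ± 1.45 against 215 ± 18.7 (-1.41 ± 0.06), and Mixl1 was lower (-5.50 ± 0.64). Otx2 was higher, 147 ± 4.08 CPM against 23.1 ± 8.93 (2.65 ± 0.16, adjusted p = 6.27e-10), as were Sox2 (1.91 ± 0.25) and Foxd3, a factor of the primed epiblast (5.57 ± 0.22). Nanog was lower (-0.52 ± 0.11), against most naive genes. Fgf4, an autocrine growth factor of pluripotent cells, was higher by 3.92 ± 0.12.

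Wnt feedback and target genes were lower in 13 of 14 (adjusted p = 4.73e-07, and adjusted p = 0.0156 with an estimated correlation), with Ccnd1 higher (0.34 ± 0.08). Wnt ligands were lower in 6 of 8 (adjusted p = 9.21e-04, and adjusted p = 0.0409 with an estimated correlation), with Wnt3a at -5.44 ± 0.32 (-6.10 without early replicate 1 of 72 h). Tailbud genes were lower in 11 of 14 (adjusted p = 1.31e-07, and adjusted p = 0.0646 with an estimated correlation), including Cdx2 (-5.18 ± 0.39) and Cdx1 (-6.33 ± 0.59, and -5.54 without control replicate 3 of 72 h). Streak genes were lower in 9 of 13 (adjusted p = 0.00209, and adjusted p = 0.432 with an estimated correlation), against Nodal (0.76 ± 0.18) and Tdgf1 (1.52 ± 0.23), which were higher. Nodal pathway genes were higher in 6 of 8 (adjusted p = 0.00166, and adjusted p = 0.103 with an estimated correlation). Naive genes were higher in 11 and lower in 2 of 15 (adjusted p = 1.53e-05, and adjusted p = 0.126 with an estimated correlation), with Dppa5a at 2.10 ± 0.10 and Tfcp2l1 at -0.85 ± 0.09. Formative genes were higher in 9 of 14 (adjusted p = 9.21e-05, and adjusted p = 0.0324 with an estimated correlation), with Fst lower (-1.82 ± 0.20). At 9 of 13 formative genes control replicate 3 of 72 h was below both other controls, and at 4 above both. General pluripotency genes were higher in 7 of 10 (adjusted p = 0.00267, and adjusted p = 0.197 with an estimated correlation), with Lin28a lower (-0.17 ± 0.06). Lin28a was not called without control replicate 2 (adjusted p = 0.0767) or 3 (0.142) or early replicate 1 (0.074) or 2 (0.0538) of 72 h, nor without the 3 control libraries numbered 3 (0.0544).

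Further lists were also higher in the early arm at 72 h. Epithelial adhesion genes were higher in 8 of 12 (adjusted p = 0.0154, and adjusted p = 0.31 with an estimated correlation). Proliferation genes were higher in 9 of 12 (adjusted p = 2.70e-04, and adjusted p = 0.102 with an estimated correlation), with Ccnb1 at 0.39 ± 0.06. Hypoxia and glycolysis genes were higher in 7 of 14 (adjusted p = 9.84e-04, and adjusted p = 0.245 with an estimated correlation), with Pfkp at 1.51 ± 0.06. Extraembryonic endoderm genes were higher in 6 of 11 (adjusted p = 0.0146, and adjusted p = 0.389 with an estimated correlation), with Dab2 at 1.40 ± 0.28. Endothelium and blood genes were higher in 7 of 11 (adjusted p = 0.0255, and adjusted p = 0.31 with an estimated correlation), with Pecam1 at 2.12 ± 0.20 and Lmo2 lower (-2.25 ± 0.25). Neither of these lists passed without the 3 control libraries numbered 3 (adjusted p = 0.067 and 0.0614). Primordial germ cell genes were higher in 5 of 8 (adjusted p = 0.00267, and adjusted p = 0.0699 with an estimated correlation), with Dazl at 2.04 ± 0.16, although Dppa3 and Prdm14 also stand in the naive list. The 3 measured genes of the two-cell-like state, Zscan4c, Zscan4d and Zscan4f, were higher by 2.05, 2.74 and 3.12 (adjusted p = 0.0418, and adjusted p = 0.381 with an estimated correlation), and as near-identical copies they may share reads. In all, 3473 genes were higher and 3723 lower, 1908 by at least 2-fold, with 57.4% of genes separated against 10% by chance. Adjusted over the list alone, 7 extraembryonic endoderm genes were higher, and 12 tailbud and 10 streak genes were lower. The share of called genes that were higher was 48.3%, and 37.8% on the log2(FPKM + 1) scale.

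The comparison at 96 h asks how the arms differed at the last age. Tbx6 was at 1.104 ± 0.434 CPM in the early arm against 201 ± 88.96 (-7.51 ± 0.35, adjusted p = 4.71e-12), Msgn1 at 0.125 ± 0.0365 against 148 ± 88.9 (-10.16 ± 0.68), and Cdx2 at 3.55 ± 0.566 against 283 ± 70.3 (-6.32 ± 0.27). Meox1 was 422-fold (95% interval 116 to 3487) lower, 264-fold (72.9 to 2184.5) without early replicate 2 of 96 h and at least 195-fold without early replicate 3 of 96 h. Otx2 was higher, at 104 ± 6.68 against 1.92 ± 0.557 CPM (5.71 ± 0.23, adjusted p = 6.46e-13), as were Nanog (3.91 ± 0.13), Eomes (6.04 ± 0.48), Fgf5 (5.55 ± 0.33) and Pou5f1 (1.88 ± 0.23). T did not pass the test, at 554 ± 82.4 CPM in the early arm and 625 ± 139 in the controls (-0.18 ± 0.15, adjusted p = 0.318). Without control replicate 3 of 96 h T was called lower (-0.33, adjusted p = 0.0228), as with no filter (-0.16, adjusted p = 0.00812), its levels being 747, 653 and 473 CPM in control replicates 1, 2 and 3.

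All 12 Hox genes of groups 1 to 4 (adjusted p = 1.53e-06, and adjusted p = 0.121 with an estimated correlation) and all 12 of groups 5 to 9 (adjusted p = 4.74e-07, and adjusted p = 0.121 with an estimated correlation) were lower. Hoxb5, Hoxb6, Hoxc5 and Hoxc8 were at 0 in all 3 early libraries and at least 323-, 333-, 338- and 477-fold lower. Without control replicate 3 of 96 h Hoxb6 and Hoxc8 were at least 189.7- and 31.1-fold lower, and without control replicate 1 of 96 h Hoxc8 was at least 797-fold lower. Tailbud genes were lower in 12 of 14 (adjusted p = 3.36e-06, and adjusted p = 0.0969 with an estimated correlation). Presomitic genes were lower in 8 of 11 (adjusted p = 4.46e-05, and adjusted p = 0.163 with an estimated correlation). Notch and segmentation clock genes were lower in 9 of 11 with Hes1 higher (adjusted p = 1.01e-04, and adjusted p = 0.0268 with an estimated correlation). Hes7 (-9.69 ± 0.28, and -11.03 without early replicate 1 of 96 h) and Dll1 (-6.33 ± 0.28) were lower. Hes7 was at 0.142 ± 0.171 CPM in the early libraries of 96 h, so the SE of its fold change understates the uncertainty. All 9 retinoic acid genes were lower (adjusted p = 1.07e-04, and adjusted p = 0.0604 with an estimated correlation), with Aldh1a2 at -8.18 ± 0.75, as were 10 of 11 mesenchymal genes (adjusted p = 1.68e-04, and adjusted p = 0.091 with an estimated correlation) and 9 of 14 Wnt feedback and target genes, against Tcf7 (adjusted p = 5.02e-04, and adjusted p = 0.051 with an estimated correlation). Somite genes were lower in 5 and higher in 3 of 8 (adjusted p = 0.139).

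Nodal pathway genes were higher in all 8 cases (adjusted p = 1.02e-05, and adjusted p = 0.0428 with an estimated correlation), with Tdgf1 at 5.31 ± 0.29 and Cer1, a secreted antagonist of the anterior endoderm, at 3.18 ± 0.57 (4.58 without control replicate 2 of 96 h). Formative genes were higher in 11 of 14 (adjusted p = 1.10e-06, and adjusted p = 0.0156 with an estimated correlation). Naive genes were higher in 10 of 15 (adjusted p = 1.74e-04, and adjusted p = 0.191 with an estimated correlation), with Klf5 lower (-1.48 ± 0.25). Epithelial adhesion genes were higher in 11 of 12 (adjusted p = 2.74e-06, and adjusted p = 0.064 with an estimated correlation), including Cldn6 (2.74 ± 0.09). Definitive endoderm genes were higher in 10 of 15 (adjusted p = 0.00523, and adjusted p = 0.429 with an estimated correlation). Control replicate 3 of 96 h lay in the direction of the list calls at this age at 12 of 14 definitive endoderm and 9 of 12 epithelial genes (below both other libraries), and at 10 of 12 Hox genes of groups 5 to 9 and 12 of 14 tailbud genes (above both). It lay against them at 8 of 9 presomitic and 9 of 11 mesenchymal genes (below both). Of the definitive endoderm genes, Foxa2 was higher (2.69 ± 0.28), and Sox17, the endoderm factor, was lower (-1.47 ± 0.32). Streak genes went both ways, 6 higher, such as Gsc (4.05 ± 0.59), and 4 lower, such as Evx1 (-2.26 ± 0.25), with a median of -0.18, a positive mean and adjusted p = 0.366. Proliferation genes were higher in 7 of 12 (adjusted p = 0.0243, and adjusted p = 0.30 with an estimated correlation), with Tyms lower, and did not pass without the 3 control libraries numbered 3 (adjusted p = 0.0649).

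At this age 4726 genes were higher and 4756 lower, 3138 by at least 2-fold, with 61.2% of genes separated against 10% by chance. Calls shared with 72 h numbered 2291 higher and 2212 lower, where 1023 and 1104 would be shared by independent lists, and these contrasts share no libraries. In counts adjusted over the list alone, 1 presomitic gene was also higher and the other called lists were unchanged.

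**Figure D3:**
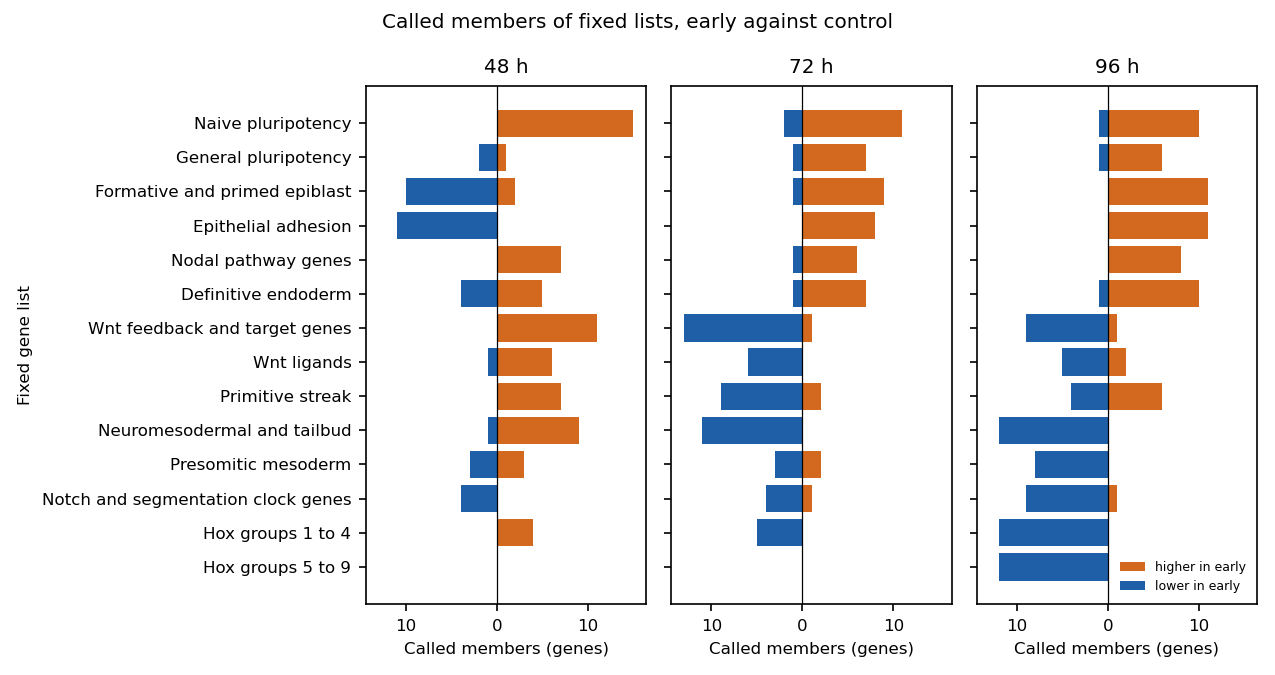
Number of measured members of 14 fixed gene lists called higher (right) and lower (left) at adjusted p under 0.05 in the early arm against the control of the same age, at 48, 72 and 96 h. At the 3 ages 15, 11 and 10 of 15 naive pluripotency genes are higher and 0, 2 and 1 lower.

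The ends of both pulses were compared as the early libraries of 48 h against the controls of 72 h. These are levels in cultures of different age. Without untreated libraries of 72 h, a different response to the pulse cannot be told apart from other changes with age. T was at 40.6 ± 4.26 CPM against 1048 ± 198 (-4.69 ± 0.18, adjusted p = 3.33e-13), Axin2 at 120.1 ± 4.09 against 215 ± 18.7 (-0.84 ± 0.06) and Wnt3a was lower after the early pulse (-5.67 ± 0.34, and -6.51 without early replicate 1 of 48 h). Zfp42 was higher by 3.11 ± 0.08 (adjusted p = 7.92e-15), and Dnmt3l, a cofactor of DNA methylation, by 5.36 ± 0.14. Naive genes were higher in 14 of 15 (adjusted p = 2.05e-07, and adjusted p = 0.0699 with an estimated correlation), against Nanog (-0.50 ± 0.11). Wnt feedback and target genes were lower in 12 of 14 (adjusted p = 2.62e-04, and adjusted p = 0.0439 with an estimated correlation). Wnt ligands were lower in 7 of 8 (adjusted p = 0.00487, and adjusted p = 0.0622 with an estimated correlation). Tailbud genes were lower in 12 of 14 (adjusted p = 2.65e-05, and adjusted p = 0.124 with an estimated correlation). Streak genes were lower in 10 of 13, with Nodal and Tdgf1 higher (adjusted p = 0.00661, and adjusted p = 0.506 with an estimated correlation). General pluripotency genes were higher in 7 of 10 (adjusted p = 0.00769, and adjusted p = 0.261 with an estimated correlation), with Lin28a lower. Nodal pathway genes were higher in 6 of 8 (adjusted p = 0.0436, and adjusted p = 0.281 with an estimated correlation), and did not pass with DESeq2 size factors (adjusted p = 0.0513). Primordial germ cell genes were higher in 4 of 8 (adjusted p = 0.0302, and adjusted p = 0.164 with an estimated correlation). Proliferation genes were higher in 11 of 12 (adjusted p = 1.22e-04, and adjusted p = 0.0832 with an estimated correlation). Epithelial adhesion genes were lower in 9 of 12 (adjusted p = 0.0229, and adjusted p = 0.335 with an estimated correlation), against Grhl2 (1.53 ± 0.08). Formative genes split evenly, 6 higher and 6 lower (adjusted p = 0.339). Between the ends of the pulses 4730 genes were higher and 5078 lower in the early arm, 3214 by at least 2-fold, with 67.1% separated against 10% by chance. Adjusted over the list alone, 8 general pluripotency genes were higher. On the log2(FPKM + 1) scale 30.1% of calls were higher, against 48.2% on counts, and the median of all genes shifted by -0.13.

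One day after each pulse, the early libraries of 72 h were set against the controls of 96 h, again at different ages and with the same limit. Cdx2 was at 0.633 ± 0.271 CPM against 283 ± 70.3 (-8.72 ± 0.34, adjusted p = 1.36e-13), and Aplnr, the apelin receptor of mesoderm, was lower (-11.41 ± 0.66). Otx2 was higher by 6.20 ± 0.23 (adjusted p = 7.58e-14) and Platr10, a non-coding RNA, by 5.46 ± 0.09. All 14 tailbud genes (adjusted p = 2.08e-07, and adjusted p = 0.0684 with an estimated correlation), all 12 Hox genes of groups 1 to 4 (adjusted p = 1.53e-05, and adjusted p = 0.162 with an estimated correlation), all 12 of groups 5 to 9 (adjusted p = 2.01e-05, and adjusted p = 0.197 with an estimated correlation) and all 11 mesenchymal genes (adjusted p = 4.68e-05, and adjusted p = 0.0699 with an estimated correlation) were lower. Notch and clock genes were lower in 9 of 11 (adjusted p = 2.27e-04, and adjusted p = 0.0305 with an estimated correlation). Presomitic genes were lower in 8 of 11 (adjusted p = 8.76e-04, and adjusted p = 0.275 with an estimated correlation) with Pcdh8 higher. Retinoic acid genes were lower in 8 of 9 (adjusted p = 6.28e-04, and adjusted p = 0.0699 with an estimated correlation). Wnt feedback and target genes were lower in 11 of 14 (adjusted p = 2.46e-04, and adjusted p = 0.0439 with an estimated correlation). Wnt ligands were lower in 5 of 8, with Wnt3 higher (adjusted p = 0.0318, and adjusted p = 0.112 with an estimated correlation). Formative genes were higher in 13 of 14 (adjusted p = 1.83e-05, and adjusted p = 0.0264 with an estimated correlation), with Fst lower. Naive genes were higher in 11 of 15 (adjusted p = 1.05e-04, and adjusted p = 0.17 with an estimated correlation), with Klf5 lower. General pluripotency genes were higher in 6 of 10 (adjusted p = 0.0159, and adjusted p = 0.31 with an estimated correlation), with Lin28a lower. Nodal pathway genes were higher in 7 of 8 (adjusted p = 2.95e-04, and adjusted p = 0.0693 with an estimated correlation). Epithelial adhesion genes were higher in 11 of 12 (adjusted p = 1.47e-04, and adjusted p = 0.111 with an estimated correlation), with Krt8 lower. The p53 response genes were higher in 6 of 11 (adjusted p = 0.0266, and adjusted p = 0.106 with an estimated correlation), such as Sesn2 (1.61 ± 0.11), with Phlda3 lower. Proliferation genes were higher in 8 of 12 (adjusted p = 0.0361, and adjusted p = 0.335 with an estimated correlation), with Tyms and Mki67 lower, and did not pass without the 3 control libraries numbered 3 (adjusted p = 0.0754). Here 5506 genes were higher and 5678 lower, 4455 by at least 2-fold, with 72.4% separated against 10% by chance. Called lists kept these counts when adjusted over the list alone.

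Within the early arm, from 48 to 72 h, Esrrb fell from 191 ± 11.1 to 60.3 ± 3.27 CPM (-1.66 ± 0.10, adjusted p = 2.57e-09) and Zfp42 by 1.48 ± 0.07, within 13 falls among 15 naive genes (adjusted p = 4.82e-07, and adjusted p = 0.0816 with an estimated correlation). Epithelial adhesion genes rose in 10 of 12 (adjusted p = 7.49e-06, and adjusted p = 0.0684 with an estimated correlation), with Krt18 at 2.06 ± 0.15 and Cldn3 at 2.10 ± 0.23, against Grhl2. Formative genes rose in 10 of 14, Fgf5 by 1.12 ± 0.24 and Pou3f1 by 1.35 ± 0.09, against Grhl2 (adjusted p = 0.0023, and adjusted p = 0.0622 with an estimated correlation). Extraembryonic endoderm genes rose in 8 of 11 (adjusted p = 0.00744, and adjusted p = 0.347 with an estimated correlation), with Apoa1 at 3.00 ± 0.77 and Apoe falling. Definitive endoderm genes rose in 6 of 15 (adjusted p = 0.026, and adjusted p = 0.535 with an estimated correlation), with Hhex falling. Notch and clock genes rose in 5 of 11 (adjusted p = 0.0132, and adjusted p = 0.0699 with an estimated correlation), and proliferation genes fell in 7 of 12 (adjusted p = 0.0344, and adjusted p = 0.331 with an estimated correlation). Jun, an immediate early factor, rose by 2.46 ± 0.15. In this step 3327 genes rose and 3510 fell, 1380 by at least 2-fold, with 60.03% separated against 10% by chance. In counts adjusted over the list alone, 14 naive genes fell, 9 extraembryonic endoderm genes rose, 2 formative genes fell and 1 proliferation gene rose. On the log2(FPKM + 1) scale 70.3% of calls were higher, against 48.7% on counts.

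From 72 to 96 h in the early arm, T rose from 24.8 ± 2.58 to 554 ± 82.4 CPM (4.49 ± 0.18, adjusted p = 2.81e-11), Foxa2, a factor of anterior streak and endoderm, from 1.23 ± 0.392 to 19.99 ± 2.45 CPM (4.04 ± 0.32, adjusted p = 7.82e-08), Gsc, of the organizer, by 4.25 ± 0.60, Mixl1 by 3.85 ± 0.66 and Eomes by 2.05 ± 0.35. Streak genes rose in 10 of 13 (adjusted p = 4.28e-06, and adjusted p = 0.212 with an estimated correlation). Tailbud genes rose in 11 of 14 (adjusted p = 2.05e-07, and adjusted p = 0.068 with an estimated correlation). Wnt feedback and target genes rose in 9 of 14 (adjusted p = 2.69e-04, and adjusted p = 0.0439 with an estimated correlation). Wnt ligands rose in 6 of 8 (adjusted p = 2.95e-04, and adjusted p = 0.0332 with an estimated correlation), Wnt11 by 3.21 ± 0.28. Mesenchymal genes rose in 8 of 11 (adjusted p = 0.0023, and adjusted p = 0.157 with an estimated correlation), against Fn1. BMP pathway genes rose in 4 of 10 (adjusted p = 0.0358, and adjusted p = 0.361 with an estimated correlation), including Id1 (1.49 ± 0.29). Definitive endoderm genes rose in 5 of 15 (adjusted p = 0.0452, and adjusted p = 0.592 with an estimated correlation, and 0.054 without the 3 control libraries numbered 3). Naive genes fell in 9 of 15 (adjusted p = 8.76e-04, and adjusted p = 0.261 with an estimated correlation), against Nanog, which rose (0.83 ± 0.11). General pluripotency genes fell in 6 of 10 (adjusted p = 0.00643, and adjusted p = 0.25 with an estimated correlation), Sox2 by 1.19 ± 0.23. The p53 response genes fell in 7 of 11 (adjusted p = 0.00161, and adjusted p = 0.0439 with an estimated correlation), against Perp. By the edgeR quasi-likelihood test 0 of 12 Hox genes of groups 1 to 4 and 0 of 12 of groups 5 to 9 were called (adjusted p of the lists = 0.53 and 0.726), and at unadjusted p under 0.05 there were 2, Hoxb1 and Hoxb2, and 0. Gadd45g, a stress-induced gene, fell by 2.35 ± 0.27. Over this step 2826 genes rose and 2830 fell, 1151 by at least 2-fold, with 53.04% separated against 10% by chance. For counts adjusted over the list alone, 9 mesenchymal genes rose and 1 Wnt target gene fell. On the log2(FPKM + 1) scale 68.5% of calls were higher, against 49.96% on counts.

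**Figure D4:**
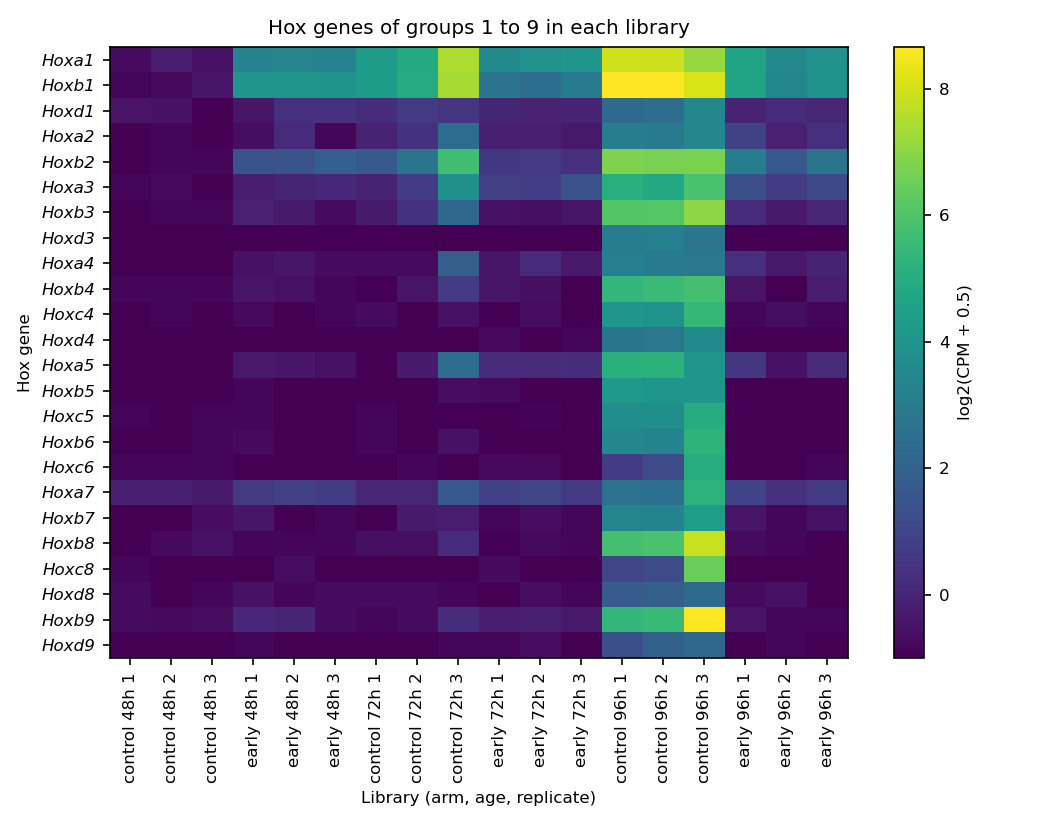
Log2 CPM (0.5 CPM added) of the measured Hox genes of groups 1 to 9 in each of the 18 libraries, 1 row per gene and 1 column per library. Means of the controls of 96 h are the highest of the 6 groups in all rows, and control replicate 3 of 96 h is above both others at 10 of 12 genes of groups 5 to 9.

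Whether the effect of pulse timing differed with age was tested as an interaction. Between 72 and 96 h the effect changed at 5383 genes, 2858 towards higher and 2525 towards lower values in the early arm. Eomes (7.17 ± 0.60) and Gsc (8.04 ± 0.85) moved up relative to the controls, and Hes7 (-8.58 ± 1.14, and -9.92 without early replicate 1 of 96 h) moved down. A second interaction set the day after the early pulse against the day after the control pulse, and 7146 genes differed, with Fgf5 at 5.66 ± 0.42 and Aldh1a2 at -9.17 ± 1.65. T did not pass this second test (0.03 ± 0.23, adjusted p = 0.943). Genes that rose on the day after both pulses numbered 1227, where 914.7 would be shared by independent lists, and 1418 fell after both, where 961 would be. Of opposite changes, 913 genes rose after the early and fell after the control pulse (910.9 for independent lists), and 641 did the reverse (965). The correlation of both changes across all tested genes was 0.101.

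Of the members named above as moving against their lists, some were not called under at least 1 alternative or without 1 library, with the highest adjusted p in parentheses. These were Greb1 (0.279) and Etv1 (0.849) at 48 h, Tyms (0.666) at 96 h, Nodal (0.12) at the ends of the pulses, and Pcdh8 (0.0913), Tyms (0.128) and Mki67 (0.115) one day after. In the steps of age they were Hes1 (0.0913) in the controls from 72 to 96 h, and Grhl2 (0.346), Apoe (0.25), Hhex (0.133), Fn1 (0.242) and Perp (0.117) in the early arm.

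Several named genes overlap another annotated gene, so their counts are uncertain. The strand setting of the counting, which bears on overlaps on opposite strands, is not given in the sources used here. Reads shared by genes on the same strand are ambiguous under any strand setting. Otx2 overlaps Otx2os1, Evx1 overlaps Evx1os, Axin2 overlaps Gm11670, Pou5f1 overlaps Gm19553 and Hoxb5 overlaps Hoxb5os, each on the opposite strand, while Hoxc5 overlaps Hoxc10 and Hoxd3 overlaps Hoxd4 on the same strand. In the mm10 build, T lies on chromosome 17, 8434423 to 8442496, Axin2 on chromosome 11, 108920349 to 108950783, Nanog on chromosome 6, 122707489 to 122714633, Otx2 on chromosome 14, 48657677 to 48673819, Cdx2 on chromosome 5, 147300805 to 147307270, Tbx6 on chromosome 7, 126781483 to 126785560 and Msgn1 on chromosome 12, 11208360 to 11208972.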

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

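Of the tests below, those chosen only after the result was seen are the correlation of deviations between ages, the correlations with a later stage, the number of genes called between the early libraries of 96 h and the controls of 72 h, the count of Wnt target genes between them, and both tests of the response at the end of the early pulse.

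The control libraries numbered 3 stood apart from replicates 1 and 2 at each age. Thinned to the lowest depth, their chi-square per degree of freedom stayed at least 4.09 times that between replicates 1 and 2. Fewer counts lower this measure, so the lower depth of these libraries would not by itself raise it. The raised values therefore argue against depth alone as the cause. The thinning could not have pointed to depth and adds nothing to this. Trends with GC content and gene length took at most 7.26% of the variance of their deviations. One bias shared by the 3 libraries as the whole cause is argued against by a correlation of 0.0303 between 48 and 96 h, while 0.368 between 48 and 72 h and 0.217 between 72 and 96 h leave a shared part open. A later stage of the culture stays open, since the deviations correlated with the controls' change from 72 to 96 h by 0.287 at 72 h and -0.0619 at 96 h, and by 0.147 and -0.152 with replicates 1 and 2 exchanged in the test, where replicate 1 against 2 gave -0.263 and -0.24. A separate culture or library preparation remains a possible explanation, since the protocol names a pair of preparation codes without assigning libraries, and no other biological explanation was tested, because the labels give these libraries no distinguishing feature.

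The early libraries of 96 h lay nearest to the controls of 72 h. Between them 3635 genes were called, 1897 higher and 1738 lower in the early libraries and 600 by at least 2-fold. This count alone does not decide whether they were the same kind of sample. The spread within a group may be technical, and separate cultures of the same kind could then differ at many genes. The direction of the Wnt feedback and target genes, 10 lower and 0 higher, argues against the same kind of sample. Exchanged labels are argued against by these 10 genes, since a control at the end of its pulse would have the higher Wnt targets. The deviations of replicate 3 correlated better with those of the other control ages under the given labels, by at least 0.142. They do not decide it, since the deviations of the controls of 48 and 96 h correlated with each other by only 0.0303. Those of the early libraries of 96 h correlated with the controls of 96 h by 0.0751. Whether the early arm passed late through the change that the controls made first stays open. Its change from 72 to 96 h correlated across genes with the controls' change from 48 to 72 h (0.649) more than with that from 72 to 96 h (0.336). However, the early libraries of 72 and 96 h already lay nearest, among the controls, to those of 48 and 72 h. The difference of 0.314 is therefore not evidence apart from these distances. Of the genes that rose in the early arm from 72 to 96 h, 2046 also rose in the controls from 48 to 72 h, where 879 would be shared by independent lists, and 1535 rose in the controls from 72 to 96 h, where 777 would be.

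At the end of the early pulse 12 of 14 tailbud and 10 of 13 streak genes were lower than at the end of the control pulse, with 0 and 2 higher, and neither list passed with an estimated correlation (adjusted p = 0.124 and 0.506). That the pulse reached few gastruloids is argued against by 924 genes called at least 2-fold lower than in the untreated controls of 48 h. A pool of mostly unreached gastruloids, giving like amounts of RNA, would keep more of the untreated level. This count was weighed only after the result was seen. In addition, 14 of 15 naive genes were higher than in both control groups, which a mix of the control profiles would not give. Alone, the naive genes do not decide it, since the gastruloids reached could themselves have raised them. Whether the response was weaker as a whole stays open. Of the controls' later rise, taken as a difference in CPM, Wnt feedback and target genes reached a median of 27.1% over 10 genes (3.54% to 62.7%). Axin2 reached 53.1% and Sp5 17.7%. Tailbud genes reached 11.6% over 13 genes (-10.4% to 91.1%), streak genes 9.18% over 11 (-3.36% to 169.5%) and T 3.82%. The list medians cover only members called at least 2-fold higher over the controls' later rise and leave out the others. Choosing members by that rise can lower these medians. The shares depend on the scale, as those of T and Axin2 are larger in log2. They also set unlike changes against each other. The early rise is against untreated controls of equal age, while the later rise includes a day of culture and no untreated libraries mark its end. The age of the cells at the pulse differs between the arms by design and stays open, as untested apart from the pulse itself.

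The effect of pulse timing differed between 72 and 96 h at 5383 genes in the interaction test, up for Eomes (7.17), Gsc (8.04), Mab21l2 (6.23), Tgfbr3 (5.34) and Wnt11 (5.86), and down for Hes7 (-8.58, and -9.92 without early replicate 1 of 96 h) and Hoxb9 (-10.90). The size for Hoxb9 is uncertain, at 0.291 ± 0.368 CPM in the controls of 72 h and 0.109 ± 0.0974 CPM in the early libraries of 96 h. Hoxb5, Hoxd4 and Sv2b, with few or no counts in some groups, also differed (adjusted p = 0.00345, 0.00502 and 1.54e-06). Lists that differed downward were Hox groups 1 to 4 (adjusted p = 1.93e-06, and adjusted p = 0.121 with an estimated correlation), Hox groups 5 to 9 (adjusted p = 4.08e-09, and adjusted p = 0.0699 with an estimated correlation), mesenchymal (adjusted p = 0.00166, and adjusted p = 0.144 with an estimated correlation), neural (adjusted p = 0.00291, and adjusted p = 0.275 with an estimated correlation), Notch and clock (adjusted p = 1.02e-05, and adjusted p = 0.0156 with an estimated correlation), presomitic (adjusted p = 5.88e-06, and adjusted p = 0.121 with an estimated correlation), retinoic acid (adjusted p = 2.33e-06, and adjusted p = 0.0332 with an estimated correlation) and somite genes (adjusted p = 1.39e-04, and adjusted p = 0.121 with an estimated correlation). Lists that differed upward were epithelial (adjusted p = 3.96e-06, and adjusted p = 0.067 with an estimated correlation), formative (adjusted p = 2.95e-04, and adjusted p = 0.038 with an estimated correlation), Nodal pathway (adjusted p = 2.72e-04, and adjusted p = 0.0684 with an estimated correlation) and streak genes (adjusted p = 2.70e-05, and adjusted p = 0.272 with an estimated correlation). For example, 9 of 11 Notch genes and 10 of 13 streak genes were called, and adjusted over the list alone 8 Hox genes of groups 5 to 9, 7 neural and 6 Nodal genes were.

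The day after the early pulse differed from the day after the control pulse at 7146 genes, up for Calcr (5.28), Eomes (5.36), Fgf5 (5.66), Grm6 (5.32) and Mmp25 (5.20), and down for Aldh1a2 (-9.17), Hoxb9 (-9.38) and Slc38a8 (-8.56). The size for Hoxb9 is again uncertain, at 0.291 ± 0.368 CPM in the controls of 72 h. Foxc2 and Sost, at few or no counts in some groups, also differed (adjusted p = 0.0322 and 0.0333). Downward lists were Hox groups 1 to 4 (adjusted p = 6.42e-06, and adjusted p = 0.142 with an estimated correlation), Hox groups 5 to 9 (adjusted p = 4.73e-07, and adjusted p = 0.121 with an estimated correlation), FGF feedback (adjusted p = 0.0266, and adjusted p = 0.102 with an estimated correlation), mesenchymal (adjusted p = 3.50e-04, and adjusted p = 0.108 with an estimated correlation), tailbud (adjusted p = 7.94e-05, and adjusted p = 0.15 with an estimated correlation), Notch and clock (adjusted p = 6.98e-04, and adjusted p = 0.038 with an estimated correlation), presomitic (adjusted p = 2.10e-04, and adjusted p = 0.212 with an estimated correlation), retinoic acid (adjusted p = 3.95e-05, and adjusted p = 0.0475 with an estimated correlation), somite (adjusted p = 0.00499, and adjusted p = 0.262 with an estimated correlation) and Wnt feedback and target genes (adjusted p = 0.0297, and adjusted p = 0.155 with an estimated correlation). Upward lists were epithelial (adjusted p = 3.11e-08, and adjusted p = 0.038 with an estimated correlation), formative (adjusted p = 2.08e-07, and adjusted p = 0.0156 with an estimated correlation), immediate early (adjusted p = 0.0456, and adjusted p = 0.367 with an estimated correlation, and 0.206 without the 3 control libraries numbered 3), Nodal pathway (adjusted p = 3.91e-04, and adjusted p = 0.0699 with an estimated correlation) and p53 response genes (adjusted p = 0.00332, and adjusted p = 0.0585 with an estimated correlation). Here 12 of 14 formative genes were called, 13 when adjusted over the list alone.

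Exchanging libraries between the arms in 60 drawn splits gave as many genes in 1 split of each interaction, the real one. The real fits called 4801 and 6825 genes and the highest others 4785 and 6242, each from exchanging 1 library in the first pair. Exchanging libraries in 1 pair left the difference between the arms in the other pair in place, so these splits do not decide whether chance gave the counts of the interactions. For the pairwise comparisons 10 splits are too few for a share under 0.05. Real values, each against a highest other split of 0, were 7482, 7431 and 7838 for early against control at 48, 72 and 96 h, 9500 at the ends of the pulses, 10395 one day after, 9261 and 6830 for the steps of the controls, and 8554 and 6992 for those of the early arm.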

How the results depend on the processing

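Of the alternatives below, leaving out the 3 control libraries numbered 3 was chosen only after the result was seen. Requiring at least 2-fold left 1854, 1908 and 3138 genes for early against control at 48, 72 and 96 h, 3214 at the ends of the pulses, 4455 one day after, 3328 and 2676 for the control steps, 1380 and 1151 for the early steps, and 1865 and 2705 for the interactions. Of 134 list calls, 29 remained with an estimated correlation, and fry called 256, the 134 among them. Without the 3 control libraries numbered 3, counts were 1.02 to 1.33 times as large, 133 lists were called and 127 of the 134 remained. Of 45 pairs of libraries with the same replicate number, 3 correlated above 0.1, and medians were 0.024 against -0.008 for other pairs. Best correlated with their own number were 12 of 18 libraries, where unrelated libraries would give about 1 of 3. A weak pairing by number therefore stays open. With a replicate block the model called 7195 genes at 48 h, and 1.01 to 1.05 times the main counts over the contrasts. Size factors gave 0.986 to 1.00 times the count, the filters 0.941 to 1.07, DESeq2 0.940 to 0.972, only the groups compared 0.776 to 1.25, log2(FPKM + 1) 0.710 to 0.824 with 74 genes turned, and 1 library left out 0.782 to 1.13. With log2(FPKM + 0.1) the share of higher calls in the interactions was 65.1% and 63.9%, against 53.1% and 51.2%, and the median of all genes shifted by -0.15 at the ends of the pulses, 0.11 in the first early step and 0.11 in the second interaction. No called list's mean changed direction under any scaling. The value of T in the second interaction, 0.03, turned to -0.12 without control replicate 2 of 72 h, -0.13 without control replicate 3 of 96 h, -0.027 and -0.029 without early replicate 2 of 48 h and replicate 3 of 72 h and -0.021 without the control libraries numbered 3, and was 0.18 at most, without control replicate 1 of 96 h.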

Other observations

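Of BMP pathway genes at 48 h, Msx2 (2.81 ± 0.58, and 3.90 without control replicate 1 of 48 h) and Id1 (1.45 ± 0.37), a direct BMP response gene, were higher than in the untreated controls. Msx1 (-2.56 ± 0.63) was lower, and the list did not pass (adjusted p = 0.912), with 3 of 10 members higher and 2 lower. In the early arm from 72 to 96 h, 4 of 10 members rose.

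Immediate early and heat shock genes fell in 6 of 11 in the controls from 72 to 96 h and rose in 1, Fos (1.27 ± 0.49), without the list passing (adjusted p = 0.117). Fos was not called by DESeq2 (adjusted p = 0.0592), with only the groups compared (0.15) or on log2(FPKM + 1) of all genes (0.13), nor without control replicate 1 (adjusted p = 0.15) or 2 (0.0808) of 72 h or replicate 1 (0.185) or 2 (0.107) of 96 h. Egr1, a growth factor response gene, was at -1.83 ± 0.21. Such genes respond within minutes to handling, and the labels do not give the time between collection and freezing.

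Sox17, of definitive endoderm and endothelium, rose in the controls from 72 to 96 h (3.28 ± 0.40).

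Lists that passed in no contrast were cardiac and anterior mesoderm (10 measured members, lowest adjusted p = 0.329), trophoblast (6 members, lowest adjusted p = 0.446), mitochondrially encoded (6 members, lowest adjusted p = 0.340) and replication-dependent histone genes (6 members, lowest adjusted p = 0.0644). Histone transcripts without a polyA tail are poorly captured in polyA RNA. Of Hox groups 10 to 13, only Hoxd13 and Hoxc13 were measured. Hoxd13 was higher in the early arm at 72 h (1.18 ± 0.33), against a low level of 0.670 ± 0.310 CPM in the controls of 72 h.

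Uncalled lists with a median and a mean of opposite sign included BMP pathway, definitive endoderm and endothelium genes at 48 h, cardiac, immediate early, retinoic acid and trophoblast genes at 72 h, and streak and trophoblast genes at 96 h. No called list had a median, mean and test of differing sign.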
